A study of Mus musculus with 8 samples.

How the data were processed

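RNA from 4 mouse cell types, with 2 samples each, was labelled with Cy3 and hybridised to 1-colour Agilent arrays. Per the file headers the scanner files come from Agilent Feature Extraction 10.1.1.1, and the deposited processed signal is a fluorescence intensity, background subtracted and detrended within each array and not scaled between arrays. The deposited mean spot signal and local background are also an intensity, and other deposited columns hold 0 or 1 marks for spots well above background, saturated or non-uniform. The deposited value table holds log2 values of all 8 arrays. Its sorted columns agree within 0.002, so the authors' log2 values were quantile normalised between arrays, and they track the signal without background subtraction. Per the submitters' processing notes R 2.11.1 and limma 3.4.3 were used, and the exact steps are not stated.

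Of 43379 gene spots, repeated spots were averaged to 41174 probes, and 427 probes marked as outliers on any array were left out, leaving 40747. Probes were named through a reference gene table (assembly GRCm38.p6, names only): 22973 by accession, 6644 by symbol and 3105 by synonym, 79.5% in all, and 8452 kept the name in the files. Probe positions are on the mm7 build, per the file headers. Processed signals were taken to log2 and shifted to equal 75th percentiles, with the mean level kept. Probes well above background on at least 2 of the 8 arrays were kept, and each gene took its brightest probe, which left 25841 genes. Of 8412 genes with several probes, 5487 had a called probe for NPC against ES, and 304 of these had called probes in both directions. Array limits: the 75th percentile of signal ran from 879 on an NPC array to 2555 on a proB array, the net signal of negative controls was 44.7 and 50.1 on the NPC arrays and from 23.0 to 26.7 on the others, and the number of arrays limits the precision.

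Slides and scan days were read from the files: ES replicate 1 and both liver arrays shared slide 1, ES replicate 2 and proB replicate 2 shared slide 2, the NPC arrays were on slide 3 and proB replicate 1 was on slide 4. The NPC arrays were scanned on another day. The differences between replicates correlated at -0.062, 0.00031 and 0.028 between types. These values gave no sign that replicate numbers paired samples but cannot exclude it, and the main fit treated samples as unpaired. The design was to fit all 8 arrays. After the values were seen, the NPC arrays, which differed by less than repeated spots do (but by 1.96 times the variance expected from spots over probes with 10 spots), were averaged and counted as 1 sample, so that the fit held 7 samples with 3 residual degrees of freedom.

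Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, prior degrees of freedom 2.62), with Benjamini-Hochberg adjustment over genes. A call is an adjusted p under 0.05, and the count with at least a 2-fold difference is given beside it. A fold for a gene detected on both arrays of one type and on no array of the other is a lower bound, taken against the lowest signal called well above background. Lists of genes, 37 in number and fixed before the data were examined along with the comparisons, the test, the rule for named genes and most of the alternative settings, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of 222 list tests 126 passed, and 0 passed with an estimated correlation (54 at an unadjusted p under 0.05), while fry, which asks whether the genes of a list move on balance one way, called 178. For each comparison with ES, 9 of 37 lists passed in NPC, 25 in liver and 25 in proB; the text describes all 9 in NPC and in the others those closest to the type, its cell mixture and the cell state, and the plot of list medians shows the rest. Named genes are the 5 highest and lowest measured, the 5 with the largest bounds per direction, up to 3 called members per list, 3 per direction between differentiated types and 6 per type among restricted genes. Pou5f1, Sox2, Klf4 and Myc are given in every comparison with ES, since the strain label of ES replicate 1, liver and proB carries the tag 4f2a. Other members are named for what the list's name covers and were chosen after their values were seen, such as Sall4, Cd19, Col1a1 and Dcn.

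The fit was tested on simulated data with each gene's variance and 200 changed genes among 25841. The simulated samples of all types had the same spread for a gene, and genes varied independently, as the fit assumes. The shares below therefore do not show how the fit behaves where ES samples vary more than the others, as they did in the data. For NPC against ES, 0% of genes changed 2-fold, 37.3% of those changed 4-fold and 95.5% of those changed 16-fold were called in the right direction. For liver against ES the shares were 0, 74.6 and 97.0%, and for proB against ES 0, 79.1 and 97.0%. In these runs 0 unchanged genes were called for NPC against ES, 16 for liver against ES and 6 for proB against ES. With as many genes changed as were called in the data, the shares for NPC against ES were 62.6, 95.3 and 99.6%, and 3.09% of calls were unchanged genes. Alternatives were normexp background correction (offset 50), quantile normalization, a shift to equal medians, the authors' values, other filters, the mean of probes, blocks for replicate and slide, an intensity trend, a floor of 16, each comparison's groups alone and leaving out each array. With slide as a fixed block, liver against ES rests on ES replicate 1 alone, the fold changes being those without ES replicate 2. There proB against ES rests on ES replicate 2 and proB replicate 2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.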

Results

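Gene expression was measured in mouse embryonic stem (ES) cells, neural progenitor cells (NPC), liver and pro-B cells (proB), with 2 arrays per type and 8 in all. The ES cells were of the V6.5 line, the NPC were derived from embryoid bodies and grown with FGF and EGF, the liver was dissociated tissue, and the proB were CD19-positive bone marrow cells, which the labels say were then plated on OP9 stromal cells, without saying at which stage the RNA was taken. The strain label carries the tag 4f2a on ES replicate 1 and on the liver and proB samples, and not on ES replicate 2 or the NPC, so the ES replicates differ in it. Each array held 41174 distinct gene probes. Between 87.8 and 93.5% of the probes were well above background on the ES, liver and proB arrays, against 68.9 and 70.6% on the NPC arrays. No spot was saturated. The number of arrays limits the precision of every value.

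Replicate arrays correlated across genes with r = 0.969 in ES, 0.993 in NPC, 0.992 in liver and 0.993 in proB, where genes are not independent replicates. Between types the correlations ran from 0.737 (NPC with liver) to 0.871 (NPC with ES). The NPC arrays differed by an SD of 0.0367 (log2) over bright genes, less than the 0.0572 between repeated spots within an array, although over bright probes with 10 spots the variance between them was 1.96 times what the spots alone give (21.1 to 327 times in the other types). They were counted as 1 sample, so that NPC values have no SD and their p-values assume that NPC vary like the other types. ES, liver and proB entered with 2 samples each, and nothing in the labels says that these came from separate cultures or animals. Their p-values measure the spread between these samples, which may be technical. The fit pools that spread over the types, and the ES arrays differed most. Over bright genes the SD between arrays was 0.390 in ES, 0.166 in liver and 0.144 in proB, and the 327 times above is that of ES. The p-values for liver against proB thus also carry the ES spread. Those for comparisons with ES rest on a spread averaged with the smaller ones of liver and proB, so they can be too low. Fitted on the compared groups alone, with fewer samples, 14479 genes passed for liver against ES (16043 in the main fit). For proB against ES 8823 passed (10581), and for liver against proB 19145 (16635). Levels below are normalised log2 signals, and fold changes are given on the log2 scale as estimate ± SE. They are not centred, and the median over all genes was -0.18 for NPC against ES, 0.31 for liver against ES and -0.16 for proB against ES. Among the other pairs that median was -0.52 for NPC against liver, -0.03 for NPC against proB and 0.43 for liver against proB.

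The study's title sets the question of how the expression state of a pluripotent cell differs from that of differentiated types, and the comparisons with ES address it. In NPC, some genes of glia and neural stem cells were among those furthest above their ES level. Mlc1, which encodes a membrane protein of astroglia, was 1685-fold higher (10.72 ± 1.00, adjusted p = 0.00121). Fabp7, the brain fatty acid binding protein of radial glia, was 971-fold higher (9.92 ± 0.62, adjusted p = 0.000425), and Bcan, the brain proteoglycan brevican, 578-fold (9.18 ± 0.97). Pantr1, a noncoding RNA, and Ptpro, a receptor phosphatase, were 892- and 698-fold higher. Among genes detected in NPC alone of the pair, Dcpp2 was at least 396-fold higher, Nr2e1, a nuclear receptor of neural stem cells, at least 155-fold, Nptx1 at least 141-fold, and the protocadherins Pcdhb11 and Pcdha4 at least 61.5- and 32.0-fold. With normexp background correction Pcdha4 lost its call (3.28, adjusted p = 0.053).

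The genes lowest in NPC that were measured in both types were Rps4l (-10.84 ± 0.37), Chchd10 (-9.53 ± 0.48), Spp1, which encodes osteopontin (-9.31 ± 0.40), the imprinted noncoding RNA Meg3 (-8.71 ± 0.45) and the threonine dehydrogenase gene Tdh (-8.62 ± 0.33). Zfp42, a classical marker of ES cells, was detected in ES alone and at least 1349-fold lower in NPC. Tex19.1, Cdh1 (E-cadherin), Tfcp2l1 and Ooep were at least 651-, 581-, 574- and 462-fold lower.

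Among 29 genes of the pluripotency network, 1 rose, 25 fell and 3 did not pass the test (1 higher and 25 lower adjusted over the list alone). The median log2 fold change was -7.28 (-6.82 with genes detected in 1 type at their bound), camera adjusted p = 2.63e-12 and adjusted p = 0.128 with an estimated correlation. The median was -4.84 with normexp and -4.76 among genes above background on all 8 arrays. The member that rose was Sall4 (1.14 ± 0.24). Pou5f1, which encodes Oct4, fell by 8.13, and Sox2, which is also a regulator of neural progenitors, was at 14.52 in ES and 14.32 in NPC (adjusted p = 0.678). Klf4 fell by 2.93 and Myc rose by 4.86 (adjusted p = 0.0135), a call that ended when NPC and ES were fitted alone (adjusted p = 0.0554). Of 39 neural progenitor markers, 25 rose, 2 fell and 12 did not pass the test (27 higher and 2 lower adjusted over the list alone). Their median log2 fold change was 3.02, camera adjusted p = 6.59e-09 and adjusted p = 0.313 with an estimated correlation. Gpm6a, a neuronal and glial membrane glycoprotein, followed Fabp7 and Bcan (7.40 ± 0.29). The astrocyte and oligodendrocyte list missed the test: of 21 genes, 7 rose, 5 fell and 9 did not pass the test (7 higher and 6 lower adjusted over the list alone), with a median of -0.03, camera adjusted p = 0.27 and adjusted p = 0.83 with an estimated correlation.

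Genes of cholesterol synthesis were mostly higher in NPC: of 23 members, 16 rose, 2 fell and 5 did not pass the test (18 higher and 2 lower adjusted over the list alone), led by Tm7sf2 (3.66), Hsd17b7 (3.24) and Nsdhl (3.00). With a median log2 fold change of 1.49, the list had a camera adjusted p = 1.73e-06 and adjusted p = 0.313 with an estimated correlation. It was also higher in liver than in ES (median 2.22, camera adjusted p = 7.36e-06). In fatty acid oxidation, 12 rose, 1 fell and 10 did not pass the test, out of 23 genes (12 higher and 1 lower adjusted over the list alone), with Acadl at 4.27 and Acaa2 at 2.75. The list had a median of 0.89, camera adjusted p = 0.00212 and adjusted p = 0.73 with an estimated correlation. Without ES replicate 1 the median was 1.37, and with the filter on all 8 arrays 1.35. Notch, FGF and Wnt signalling genes went both ways: of 39, 18 rose, 6 fell and 15 did not pass the test (19 higher and 8 lower adjusted over the list alone). Hes5, a Notch target of neural progenitors, rose by 5.81. Members had a median log2 fold change of 1.30, camera adjusted p = 0.00972 and adjusted p = 0.459 with an estimated correlation. With normexp the list no longer passed (median 1.22, adjusted p = 0.321).

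Early lineage regulators were lower in NPC, where 1 rose, 13 fell and 11 did not pass the test, out of 25 (2 higher and 14 lower adjusted over the list alone). Over the list the median was -1.23 (-1.03 with genes detected in 1 type at their bound), camera adjusted p = 0.00796 and adjusted p = 0.73 with an estimated correlation. The keratins Krt18 and Krt8 fell by 7.69 and 5.23, and Nodal, a signal of the early embryo, fell by 4.32. With normexp this list's median was 0.19 and the test was missed (adjusted p = 0.0543), and it was -0.69 with quantile normalization and -0.67 with the authors' values. Of 22 DNA methylation and germline genes, 2 rose, 14 fell and 6 did not pass the test (3 higher and 14 lower adjusted over the list alone). Across these genes the median was -2.62 (-2.36 with genes detected in 1 type at their bound), camera adjusted p = 0.0097 and adjusted p = 0.371 with an estimated correlation. Ddx4 and Stra8, germ cell genes, were at least 102- and 244-fold lower, and Dnmt3l, a cofactor of DNA methylation, fell by 7.57. Restricted to genes above background on all 8 arrays, the list missed the test (median -0.79, adjusted p = 0.139), and with normexp its median was -1.12. Among 24 housekeeping genes, 9 rose, 2 fell and 13 did not pass the test (9 higher and 3 lower adjusted over the list alone). Here the median log2 fold change was 0.78, camera adjusted p = 0.0118 and adjusted p = 0.607 with an estimated correlation. That call was lost with quantile normalization (median 0.37, adjusted p = 0.402), with the authors' values (0.33, adjusted p = 0.446), with normexp (0.63, adjusted p = 0.896) and with the filter on all 8 arrays (adjusted p = 0.0703).

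The fibroblast and stromal list was lower in NPC than in ES, with 12 of 28 members that fell, 2 that rose and 14 that did not pass (2 higher and 13 lower adjusted over the list alone). Its median log2 fold change was -3.88, camera adjusted p = 0.0205 and adjusted p = 0.83 with an estimated correlation. The ES samples differed from each other in these genes: 27 of the 28 members were over 1 (log2) higher in ES replicate 2 than in replicate 1, with a median difference of 3.37, while the median over the pluripotency network differed by -0.13. Other lists with a median over 0.3 higher in replicate 2 were immediate early and dissociation genes (median 0.95, 10 of 22 over 1), imprinted genes (0.58, 8 of 24), ribosome biogenesis genes (0.45, 3 of 26), Hox genes (0.39, 16 of 37) and Notch, FGF and Wnt signalling genes (0.32, 10 of 39). Col1a1, a collagen gene, was at 12.95 in replicate 1 and 16.50 in replicate 2, and Dcn, which encodes decorin, at 7.25 and 13.36. Without ES replicate 2 the list's median was -1.61 and it missed the test (adjusted p = 0.0682), and with the filter on all 8 arrays the median was -2.29.

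**Figure D1:**
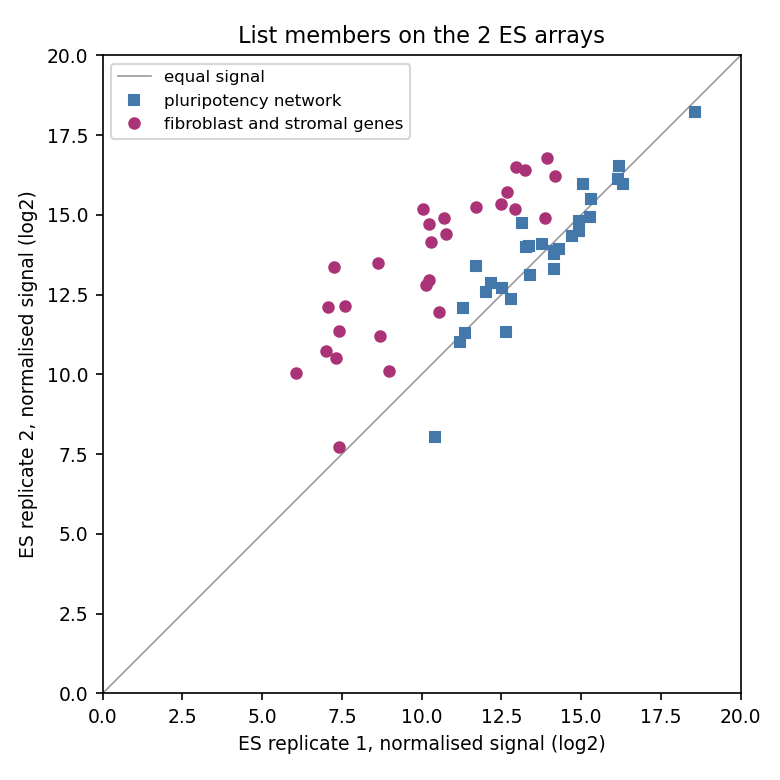
Normalised log2 signal of each member of the fibroblast and stromal list (circles) and of the pluripotency network (squares) on ES replicate 1 (horizontal axis) and ES replicate 2 (vertical axis), with a line of equal signal. The circles lie above the line by a median of 3.37, and the squares lie around it, with a median difference of -0.13.

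In all, 10630 of 25841 genes passed the test between NPC and ES with limma, 4685 higher and 5945 lower in NPC, and 9177 of them differed at least 2-fold. Of the genes called lower, 2276 were detected in ES alone. The share of calls that were higher was 44.1%, against 48.9% with quantile normalization, 51.5% with the authors' values, 54.6% with normexp, 55.7% with the filter on all 8 arrays and 59.0% with a shift to equal medians, and normexp called 2955 genes. With the filter on all 8 arrays, which drops by construction the genes detected in ES alone, 3530 genes were lower. Fitted without the other types, 2780 genes passed. The NPC arrays shared no slide or scan day with another type, so slide, day and type cannot be told apart.

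In liver, secreted plasma proteins and enzymes of drug metabolism showed the greatest differences from ES. Cyp2a5, a cytochrome P450, was 15763-fold higher (13.94 ± 0.26, adjusted p = 4.02e-06), and Hp, the hemoglobin-binding plasma protein haptoglobin, 14514-fold (13.83 ± 0.28). Serpina1b, an antitrypsin, Apoc3, an apolipoprotein, and Cyp2f2 rose by 13.75, 13.19 and 13.14. Cyp2e1, detected in liver alone of the pair, was at least 22964-fold higher, Ugt2b5 at least 9839-fold, Cyp2a12 at least 6979.8-fold, Ttr, the thyroid hormone carrier transthyretin, at least 5363-fold and Ugt2b1 at least 2557-fold. Zfp42 fell by 11.06, Psrc1 by 9.56, Tdh by 9.11, Dppa5a by 9.03 and the mitotic kinase gene Bub1 by 8.76. Fbxo15, Sox2, Dppa4, Dppa3 and Lrrc34 were detected in ES alone and at least 1917-, 1320.4-, 992-, 897- and 355-fold lower. Pou5f1 fell by 6.87 and Klf4 by 6.15, and Myc was at 10.48 in ES and 10.56 in liver (adjusted p = 0.933).

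All 39 hepatocyte secreted protein genes tested rose in liver (also 39 higher adjusted over the list alone), Alb, which encodes albumin, by 13.14. A median log2 fold change of 10.37 (10.31 with slide as a block) was found, camera adjusted p = 8.25e-19 and adjusted p = 0.146 with an estimated correlation. The 30 cytochrome P450 and drug metabolism genes also rose without exception (30 higher and 0 lower adjusted over the list alone). The median log2 fold change was 8.79 (8.91 with slide as a block), camera adjusted p = 7.54e-14 and adjusted p = 0.137 with an estimated correlation. So did the 28 enzymes of bile acid synthesis, gluconeogenesis and the urea cycle (28 higher and 0 lower adjusted over the list alone), among them Aldob (12.75), Pah (12.68) and Cps1, the first enzyme of the urea cycle (11.64). Their median log2 fold change was 7.97 (7.96 with slide as a block), camera adjusted p = 2.18e-13 and adjusted p = 0.137 with an estimated correlation. Of 23 hepatic transcription factors, 21 rose, 0 fell and 2 did not pass the test (22 higher and 0 lower adjusted over the list alone), with the nuclear receptors Ppara and Nr1h4 at 9.19 and 7.43 and the homeobox gene Prox1 at 7.53. With a median log2 fold change of 4.92 (4.50 with slide as a block), the list had a camera adjusted p = 4.74e-08 and adjusted p = 0.193 with an estimated correlation. In fatty acid oxidation all 23 genes rose (23 higher and 0 lower adjusted over the list alone), Hmgcs2, the enzyme that commits acetyl units to ketone bodies, by 9.19. The list had a median of 3.39 (3.25 with slide as a block), camera adjusted p = 2.03e-08 and adjusted p = 0.146 with an estimated correlation.

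Genes of dividing cells were lower in liver. All 28 G2 and M phase genes fell (0 higher and 28 lower adjusted over the list alone), Top2a by 9.39. Members had a median log2 fold change of -6.42 (-6.37 with slide as a block), camera adjusted p = 1.00e-18 and adjusted p = 0.146 with an estimated correlation. Of 31 DNA replication genes, 0 rose, 28 fell and 3 did not pass the test (0 higher and 28 lower adjusted over the list alone), with the replicative helicase genes Mcm2 and Mcm5 at -6.61 and -5.94. Over the list the median was -3.97 (-4.01 with slide as a block), camera adjusted p = 4.77e-14 and adjusted p = 0.137 with an estimated correlation. Ribosome biogenesis genes followed, where 0 rose, 24 fell and 2 did not pass the test, out of 26 (0 higher and 24 lower adjusted over the list alone). Across these genes the median was -2.69 (-2.39 with slide as a block), camera adjusted p = 5.26e-11 and adjusted p = 0.263 with an estimated correlation. In glycolysis, 0 rose, 14 fell and 4 did not pass the test, out of 18 genes (0 higher and 14 lower adjusted over the list alone), with Hk2, a hexokinase, at -7.42 and the glucose transporter Slc2a3 at -7.06. Here the median log2 fold change was -2.49 (-2.36 with slide as a block), camera adjusted p = 9.01e-07 and adjusted p = 0.137 with an estimated correlation. Among 29 pluripotency genes, 0 rose, 27 fell and 2 did not pass the test (0 higher and 27 lower adjusted over the list alone). Its median log2 fold change was -6.15 (-5.97 with slide as a block), camera adjusted p = 1.31e-14 and adjusted p = 0.105 with an estimated correlation. Polycomb and related chromatin genes were mostly lower, and 5 rose, 17 fell and 6 did not pass the test, out of 28 (5 higher and 18 lower adjusted over the list alone), with the methyltransferase gene Ezh2 at -4.69 and Phc1 at -6.45. A median log2 fold change of -1.35 (-1.37 with slide as a block) was found, camera adjusted p = 7.81e-05 and adjusted p = 0.137 with an estimated correlation. With normexp that median was -0.62. Among 30 histone acetyltransferases, deacetylases and enhancer methylases, 4 rose, 18 fell and 8 did not pass the test (4 higher and 19 lower adjusted over the list alone), with Kat6b at -3.13 and Hdac11 at 2.85. The median log2 fold change was -0.78 (-0.85 with slide as a block), camera adjusted p = 0.000516 and adjusted p = 0.137 with an estimated correlation.

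Some markers of other liver cells and of blood cells were also higher than in ES. Of 19 Kupffer cell and macrophage genes, 17 rose, 1 fell and 1 did not pass the test (17 higher and 1 lower adjusted over the list alone), with the Kupffer cell lectin Clec4f at 9.29. Their median log2 fold change was 3.96 (3.91 with slide as a block), camera adjusted p = 1.79e-05 and adjusted p = 0.263 with an estimated correlation. Of 19 endothelial genes, 18 rose, 1 fell and 0 did not pass the test (18 higher and 1 lower adjusted over the list alone), with Stab1, a scavenger receptor of sinusoids, at 7.15. With a median log2 fold change of 3.43 (3.20 with slide as a block), the list had a camera adjusted p = 4.12e-05 and adjusted p = 0.146 with an estimated correlation. The stellate cell and cholangiocyte list missed the test: of 17 genes, 7 rose, 5 fell and 5 did not pass the test (8 higher and 5 lower adjusted over the list alone). The list had a median of 0.65 (0.95 with slide as a block), camera adjusted p = 0.685 and adjusted p = 0.714 with an estimated correlation. Of blood cell lists, in myeloid and mast cell genes 15 rose, 0 fell and 9 did not pass the test, out of 24 (16 higher and 0 lower adjusted over the list alone). Members had a median log2 fold change of 1.27 (1.21 with slide as a block), camera adjusted p = 0.00179 and adjusted p = 0.146 with an estimated correlation. In mature B and plasma cell genes 16 rose, 2 fell and 5 did not pass the test, out of 23 (16 higher and 2 lower adjusted over the list alone). Over the list the median was 1.35 (1.37 with slide as a block), camera adjusted p = 0.00359 and adjusted p = 0.146 with an estimated correlation. With the authors' values these medians were 0.81 and 0.87. Erythroid genes (median 0.60, adjusted p = 0.364) and T and NK cell genes (0.65, adjusted p = 0.321) missed the test. In the fibroblast and stromal list, 2 rose, 11 fell and 15 did not pass the test, out of 28 (2 higher and 11 lower adjusted over the list alone). Across these genes the median was -2.58 (-0.78 with slide as a block), camera adjusted p = 0.00496 and adjusted p = 0.669 with an estimated correlation. This was the list in which ES replicate 2 exceeded replicate 1 by a median of 3.37. Without ES replicate 2 its median was -0.78 and the list missed the test. Slide as a block also compares liver with ES replicate 1 alone, so its -0.78 is the same contrast and not a separate check. With the filter on all 8 arrays the list missed the test as well (-2.33, adjusted p = 0.0989). Without ES replicate 1 the median was -3.89.

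Between liver and ES 16043 of 25841 genes passed the test with limma, 9426 higher and 6617 lower in liver, and 12354 differed at least 2-fold. The share of calls that were higher was 58.8%, against 50.2% with a shift to equal medians, 52.3% with the authors' values, 52.9% with quantile normalization and 61.4% with normexp. Within slide 1, which held 1 ES and both liver samples, 16548 passed, the spread being that between the liver samples alone. With normexp 10300 passed, and without liver replicate 2 the number higher was 6258.

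In proB, genes of B lymphocytes stood beside those of other blood lineages. Jchain, the joining chain of secreted immunoglobulin, was 2831-fold higher than in ES (11.47 ± 0.55, adjusted p = 7.30e-05), Hbb-bt, a beta globin, 2238-fold (11.13 ± 0.31), and S100a9, a calcium-binding protein of neutrophils, 1768-fold (10.79 ± 0.17). Lyz1, a lysozyme, and Pf4, a chemokine of platelets, rose by 10.56 and 10.51. Of genes detected in proB alone of the pair, S100a8 was at least 18650.0-fold higher, Retnlg at least 2839-fold, the neutrophil granule protein gene Lcn2 at least 1655-fold, Ear10 at least 530.5-fold and Tlr1 at least 408-fold. Zfp42 fell by 10.48, Dppa5a by 9.73, Dppa3 by 9.62, Tdh by 9.43 and Bex1 by 9.31. Sox2, Dppa4, Nr0b1, Lrrc34 and Rian were detected in ES alone and at least 2575-, 1935-, 1352-, 693- and 349-fold lower. Pou5f1 fell by 7.84 and Klf4 fell by 2.29, and Myc was at 10.48 in ES and 12.60 in proB (adjusted p = 0.0895), a difference that passed without ES replicate 2 (3.12, adjusted p = 0.0182).

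Of 32 genes of the pre-B receptor and early B cell signalling, 29 rose, 1 fell and 2 did not pass the test (29 higher and 1 lower adjusted over the list alone), with Il7r, the receptor of interleukin 7, at 10.63 and Ptprc, the leukocyte antigen CD45, at 10.28. Here the median log2 fold change was 5.67 (5.36 with slide as a block), camera adjusted p = 1.40e-18 and adjusted p = 0.0815 with an estimated correlation. Cd19, the antigen used for isolation, was at 14.58 in proB and 8.61 in ES. Among 23 pro-B transcription factors, 19 rose, 0 fell and 4 did not pass the test (20 higher and 0 lower adjusted over the list alone), with Ikzf1 (Ikaros) at 9.01, the coactivator Pou2af1 at 8.72 and Spib at 8.07. Its median log2 fold change was 3.74 (3.75 with slide as a block), camera adjusted p = 2.12e-13 and adjusted p = 0.0865 with an estimated correlation. With the filter on all 8 arrays that median was 2.08. Mature B and plasma cell genes were higher too, where 18 rose, 0 fell and 5 did not pass the test, out of 23 (19 higher and 0 lower adjusted over the list alone), with Ms4a1, the antigen CD20, at 9.62. A median log2 fold change of 6.42 (6.32 with slide as a block) was found, camera adjusted p = 2.31e-13 and adjusted p = 0.0815 with an estimated correlation. That median was above the 5.67 of the pre-B receptor list. Which stages of B cells the samples held was not tested.

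Genes of other blood cells were bright on both proB arrays. Of 24 myeloid and mast cell genes, 19 rose, 0 fell and 5 did not pass the test (20 higher and 0 lower adjusted over the list alone), with the granule genes Camp and Ngp at 13.80 and 12.70. The median log2 fold change was 6.90 (6.82 with slide as a block, 6.69 with genes detected in 1 type at their bound), camera adjusted p = 1.12e-13 and adjusted p = 0.0815 with an estimated correlation. It was 3.53 with the filter on all 8 arrays. Of 18 erythroid genes, 16 rose, 0 fell and 2 did not pass the test (16 higher and 0 lower adjusted over the list alone), with Alas2, the erythroid enzyme of heme synthesis, at 8.74 and the alpha globin Hba-a1 at a level of 18.29 in proB. Their median log2 fold change was 4.36 (3.88 with slide as a block), camera adjusted p = 3.60e-12 and adjusted p = 0.0815 with an estimated correlation. Of 19 macrophage genes, 18 rose, 0 fell and 1 did not pass the test (19 higher and 0 lower adjusted over the list alone). With a median log2 fold change of 4.47 (4.52 with slide as a block), the list had a camera adjusted p = 2.31e-13 and adjusted p = 0.136 with an estimated correlation. T and NK cell genes moved less, and 11 rose, 2 fell and 13 did not pass the test, out of 26 (11 higher and 2 lower adjusted over the list alone), with Nkg7, a granule protein, at 5.66. The list had a median of 0.42 (0.49 with slide as a block), camera adjusted p = 0.00982 and adjusted p = 0.376 with an estimated correlation. That call was lost with the filter on all 8 arrays (0.11, adjusted p = 0.188), and the median was 0.92 with the mean of probes and 0.27 with normexp.

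Interferon response genes and MHC class I genes were higher in proB than in ES. Of 24 interferon genes, 19 rose, 1 fell and 4 did not pass the test (19 higher and 1 lower adjusted over the list alone), with Rsad2, an antiviral enzyme, at 7.05. Members had a median log2 fold change of 2.37 (2.00 with slide as a block), camera adjusted p = 8.13e-09 and adjusted p = 0.0865 with an estimated correlation. Of 13 MHC class I genes, 12 rose, 1 fell and 0 did not pass the test (12 higher and 1 lower adjusted over the list alone). Over the list the median was 4.34 (4.50 with slide as a block), camera adjusted p = 4.05e-08 and adjusted p = 0.106 with an estimated correlation. Both lists were also higher in liver than in ES, with medians of 3.05 and 4.28 (camera adjusted p = 8.23e-05 and 2.31e-05). Between liver and proB neither passed (-0.04 and 0.23, camera adjusted p = 0.512 and 0.897). Genes of cholesterol synthesis and glycolysis were lower in proB than in ES. In cholesterol synthesis, 0 rose, 20 fell and 3 did not pass the test, out of 23 (0 higher and 20 lower adjusted over the list alone), with the receptor gene Ldlr at -3.30 and Hmgcs1 at -2.85. Across these genes the median was -2.06 (-1.76 with slide as a block), camera adjusted p = 2.31e-07 and adjusted p = 0.0865 with an estimated correlation. In glycolysis, 0 rose, 16 fell and 2 did not pass the test, out of 18 (0 higher and 16 lower adjusted over the list alone), with the glucose transporter Slc2a1 at -4.20. Here the median log2 fold change was -2.65 (-2.59 with slide as a block), camera adjusted p = 1.12e-07 and adjusted p = 0.0865 with an estimated correlation. The pluripotency network was lower as well, and 0 rose, 28 fell and 1 did not pass the test, out of 29 (0 higher and 29 lower adjusted over the list alone). Its median log2 fold change was -6.06 (-6.59 with slide as a block), camera adjusted p = 1.01e-15 and adjusted p = 0.0815 with an estimated correlation. In the fibroblast and stromal list, where ES replicate 2 exceeded replicate 1 by a median of 3.37, 3 rose, 12 fell and 13 did not pass the test, out of 28 (3 higher and 13 lower adjusted over the list alone), with Vcam1, an adhesion molecule, at 5.71. A median log2 fold change of -3.13 (-5.01 with slide as a block) was found, camera adjusted p = 0.0367 and adjusted p = 0.751 with an estimated correlation. Without ES replicate 1 the median was -4.89. The test was missed without ES replicate 2 (median -1.25, adjusted p = 0.439), without proB replicate 1 (-3.15, adjusted p = 0.0565), with the filter on all 8 arrays (-3.09, adjusted p = 0.216) and with a floor of 16 (adjusted p = 0.054).

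Between proB and ES 10581 genes passed the test with limma, 4584 higher and 5997 lower in proB, and 8553 differed at least 2-fold. Of the calls 43.3% were higher, against 37.0% with the filter on all 8 arrays, 42.8% with normexp, 44.6% with a shift to equal medians, 48.0% with quantile normalization and 48.2% with the authors' values. Within slide 2, which held 1 sample of each type, 10686 passed, a count that takes its spread from the liver samples and assumes that ES and proB vary like them. Without proB replicate 1 the number was 6687, without proB replicate 2 it was 6810, and with normexp 5618.

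**Figure D2:**
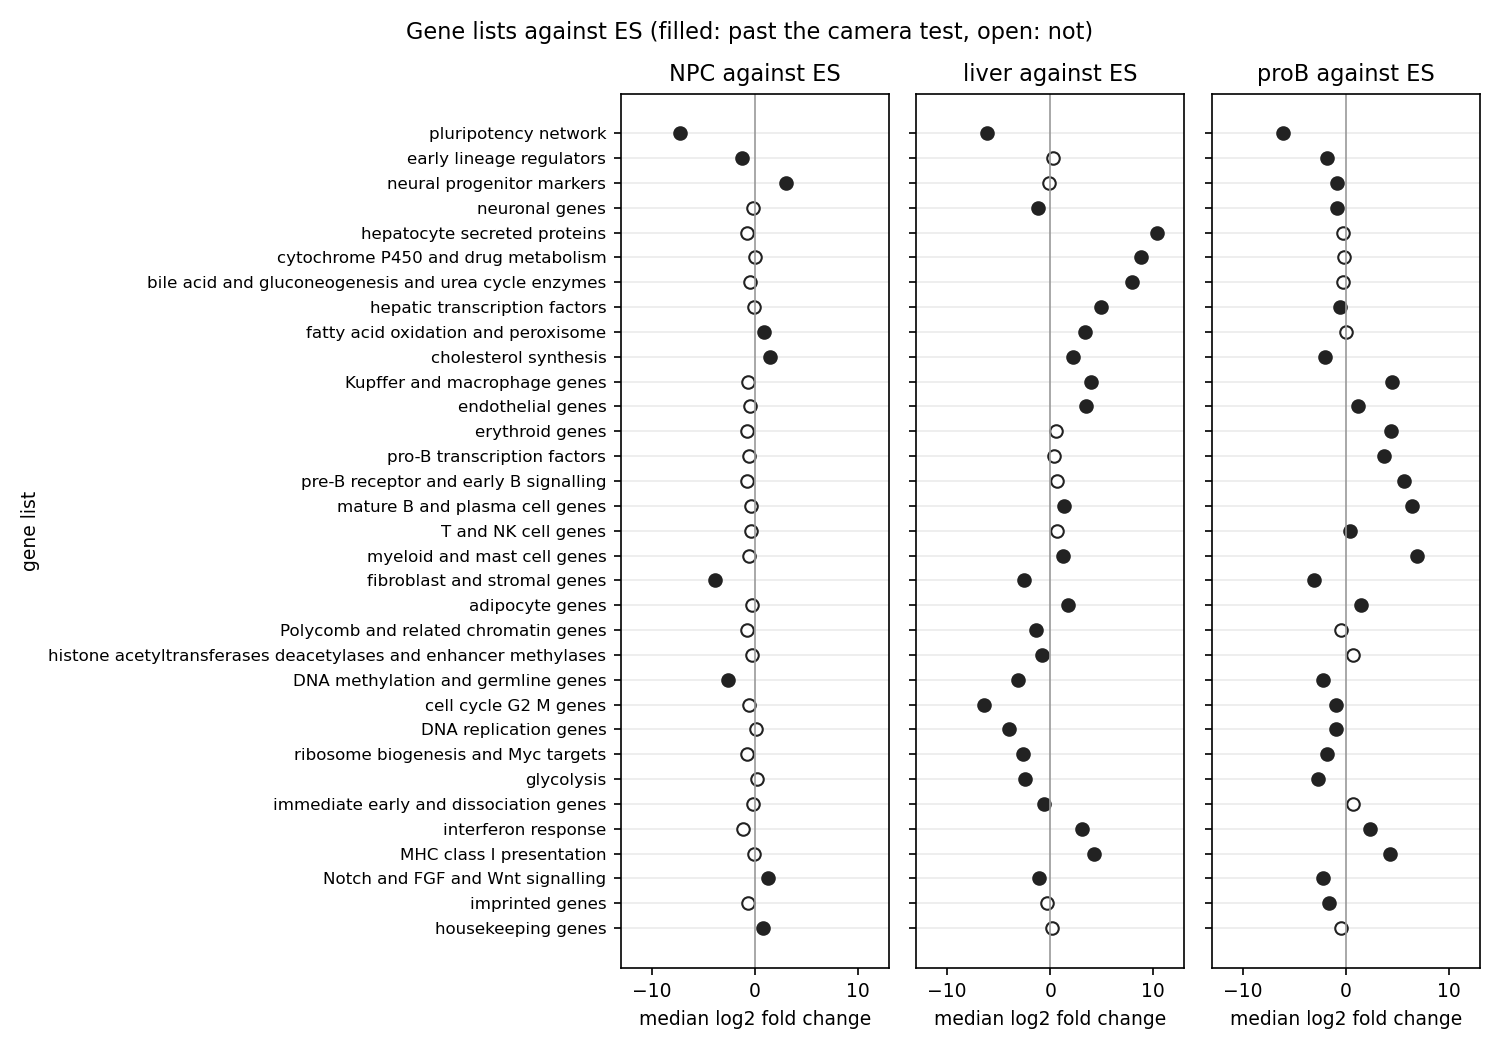
Median log2 fold change (horizontal axis) of each gene list (vertical axis) for NPC, liver and proB against ES, for lists that passed the camera test in at least 1 of these comparisons; filled points passed it in that comparison and open points did not. The pluripotency network lies at -7.28, -6.15 and -6.06, and the hepatocyte secreted proteins at 10.37 in liver.

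The differentiated types were also compared with each other. Against liver, NPC were highest in Mlc1 (11.92 ± 1.00), Phgdh, the first enzyme of serine synthesis (10.95 ± 0.30), and Kcnmb4 (10.88 ± 0.73). They were lowest in the plasma protein genes Fgg (-12.74 ± 0.87), Apoh (-12.68 ± 0.28) and Ahsg (-12.67 ± 0.28). Of 28 G2 and M phase genes, 28 rose, 0 fell and 0 did not pass the test (28 higher and 0 lower adjusted over the list alone). The median log2 fold change was 5.65, camera adjusted p = 1.02e-17 and adjusted p = 0.168 with an estimated correlation. In all 16489 genes passed, 6201 higher and 10288 lower in NPC, 14457 at least 2-fold, and 3388 of those lower were detected in liver alone. The share higher was 37.6%, against 46.4% with quantile normalization, 48.4% with the authors' values, 49.8% with normexp and 54.6% with a shift to equal medians, and normexp called 5793 genes. With the filter on all 8 arrays 6361 were lower.

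Against proB, NPC were highest in Mlc1 (13.06 ± 1.00), Bcan (11.55 ± 0.97) and Igfbp2, an insulin-like growth factor binding protein (11.49 ± 0.60). They were lowest in S100a9 (-11.38 ± 0.21), Hbb-bt (-11.01 ± 0.38) and the lysozyme gene Lyz2 (-10.50 ± 1.34). For cholesterol synthesis, 21 rose, 0 fell and 2 did not pass the test, out of 23 genes (21 higher and 0 lower adjusted over the list alone). Their median log2 fold change was 3.78, camera adjusted p = 1.08e-09 and adjusted p = 0.0952 with an estimated correlation. In all 13040 genes passed, 6592 higher and 6448 lower in NPC, and 11430 at least 2-fold. The share higher was 50.6%, against 51.7% with quantile normalization, 53.3% with the authors' values, 60.8% with a shift to equal medians and 64.3% with normexp, and normexp called 6123 genes. With the filter on all 8 arrays 3616 were lower.

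Liver exceeded proB most in Mup1, a major urinary protein (14.38 ± 1.04), Serpina1b (14.08 ± 0.26) and Apoc3 (13.64 ± 0.27), and was lowest in the antimicrobial peptide gene Camp (-11.24 ± 0.40), Fcrla (-9.71 ± 0.18) and Tnfrsf13c, the receptor of a B cell survival factor (-9.29 ± 0.73). Of 31 DNA replication genes, 2 rose, 28 fell and 1 did not pass the test (2 higher and 29 lower adjusted over the list alone). With a median log2 fold change of -2.95 (-2.92 with slide as a block), the list had a camera adjusted p = 1.12e-12 and adjusted p = 0.131 with an estimated correlation. In all 16635 genes passed, 10361 higher and 6274 lower in liver, and 12815 at least 2-fold. The share higher was 62.3%, against 52.7% with the authors' values, 53.1% with a shift to equal medians, 53.9% with quantile normalization and 69.5% with normexp. No slide held both types, and with slide as a block, a comparison that runs through the difference between the ES arrays, 12563 passed. With normexp 3480 were lower.

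A gene was called restricted to a type where it passed the test and was at least 2-fold higher than in each of the other 3. By this rule 1252 genes were restricted to ES, 1885 to NPC, 3870 to liver and 1906 to proB. Genes were ranked by their lowest fitted fold. For a gene not detected in another type that fold rests on signals not above background, so the order is not firm. The ES genes with the greatest lowest fold were Dppa4, Zfp42, Dppa3, Nr0b1, Lrrc34 and Tdh, of which Zfp42 was at least 1349-fold above any other type. In NPC they were Mlc1, Dcpp2, Bcan, Pantr1, Nr2e1 and Ecrg4, where Mlc1, at chromosome 15, 89038294 to 89038353 on the mm7 build, stood at 17.43 against 6.71 in ES. In liver they were Cyp2e1, Cyp2a5, Serpina1b, Fabp1, Ugt2b5 and Apoc3, with Cyp2e1 (chromosome 7, 137190949 to 137191008) at 17.86. In proB they were Ngp, Camp, Fcrla, S100a8, Retnlg and Hemgn, of which Fcrla is a gene of B cells, Hemgn of erythroid cells and Ngp, Camp, S100a8 and Retnlg of granulocytes. With normexp the numbers were 526, 584, 1939 and 970, and the proB number was 990 with the filter on all 8 arrays. Under a shift to equal medians 3003 genes were restricted to NPC.

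**Figure D3:**
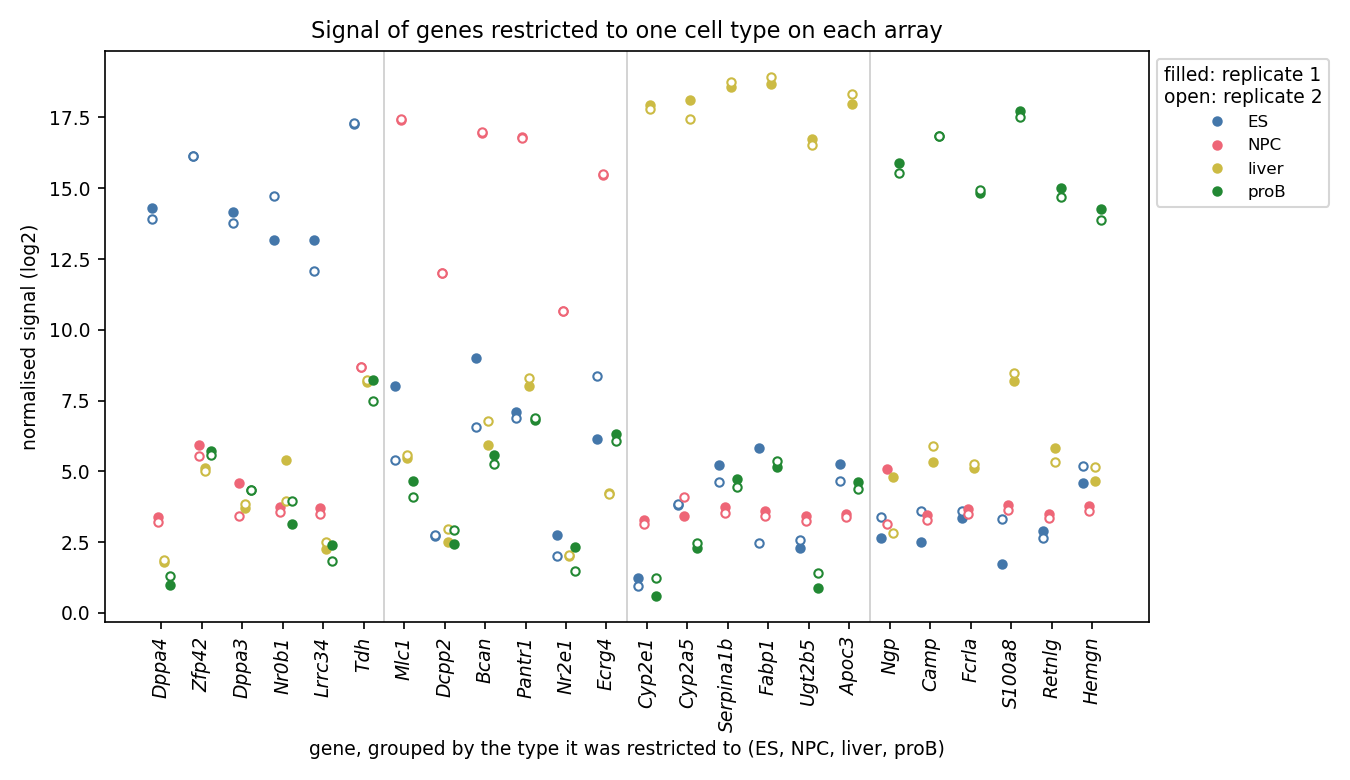
Normalised log2 signal (vertical axis) on each of the 8 arrays of the 6 genes with the greatest lowest fold per type, grouped by type, with replicate 1 filled and replicate 2 open. Each gene lies highest in its type: Dppa4 at 14.11 in ES, Mlc1 at 17.43 in NPC, Cyp2e1 at 17.86 in liver and Camp at 16.84 in proB.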

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

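These 2 settings were taken up as alternatives after the data were seen: the NPC arrays as 2 samples, which was the original design before they were averaged, and proB against ES within slide 2. Over all alternatives 584 of 624 counts stayed within 1.5 times the reported one. Some could not move: leaving out an NPC array left calls between the other types unchanged, such as 16043 for liver against ES. For proB against ES, within slide 2 repeated slide as a fixed block (10686 in both). For liver against ES, slide as a fixed block gave the same fold changes as leaving out ES replicate 2. Of list results 4612 of 4804, and of named gene results 8541 of 8730, kept their side of the threshold and, where called, their direction. Direction was not compared for results called under neither setting. Of 28 array correlations, 27 moved by less than the SD of the replicate correlations over the types. Normexp background correction moved the most; the cause was not tested. NPC against ES gave 2955 genes (1614 higher, 1341 lower, 2955 at least 2-fold), liver against ES 10300 (3979 lower), proB against ES 5618 (2404 higher, 3214 lower, 5588 at least 2-fold), NPC against liver 5793 (2886 higher, 2907 lower, 5793 at least 2-fold), NPC against proB 6123 (3940 higher, 2183 lower, 6123 at least 2-fold), and liver against proB 3480 lower. Restricted genes were 526 in ES, 584 in NPC, 1939 in liver and 970 in proB. A shift to equal medians gave 3003 restricted to NPC, cause not tested. The filter on all 8 arrays tests fewer genes and drops by construction those not detected in NPC. It gave 3530 lower in NPC than in ES, 6361 than in liver, 3616 than in proB, and 990 restricted to proB. Fitted on the compared groups alone, with fewer samples, NPC against ES gave 2780 (1131 higher, 1649 lower, 2780 at least 2-fold). Of the 222 list tests, 0 passed with an estimated correlation and 222 with fry's mixed test. 

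Results called in the main fit or in the alternative whose direction reversed, for lists that of the test relative to all genes, were these, the cause not tested. With normexp the DNA replication list in NPC against ES had a median of -0.085 (camera adjusted p = 0.0112). The bile acid, gluconeogenesis and urea cycle list in NPC against proB had 1.17 (camera adjusted p = 0.0402), so both passed the test in the reversed direction. With normexp in NPC against ES these called members of lists that did not pass also reversed: Fcgr3 0.91, Eraf 1.33, Cd83 0.62, Itgam 0.22, Epx 0.60, Kdm5d 0.44 and Sry 1.66. None of these genes was past the threshold there. With the authors' values Sry was 0.14. With slide as a fixed block the fibroblast and stromal list in liver against proB was 3.37, which follows from that block's construction, since it runs through the difference between the ES arrays. With normexp 3 lists past the test also changed the sign of their median while the test kept its direction: T and NK cell genes in NPC against proB from -1.16 to 0.37 (adjusted p = 0.0255), early lineage regulators in NPC against ES from -1.23 to 0.19 (adjusted p = 0.0543) and neuronal genes in liver against ES from -1.15 to 0.012 (adjusted p = 0.123). 

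Without 1 array at a time, the counts ranged as follows, with the lone sample assumed to vary like the other groups. For NPC against ES they ran from 8219 to 13047 changed, 3602 to 5762 higher, 4582 to 7530 lower and 7991 to 10554 at least 2-fold. For liver against ES they ran from 11209 to 17595 changed, 6258 to 10294 higher, 4951 to 7301 lower and 10597 to 13451 at least 2-fold. For proB against ES they ran from 6687 to 12266 changed, 3022 to 5235 higher, 3624 to 7249 lower and 6658 to 9476 at least 2-fold. For NPC against liver they ran from 12684 to 19098 changed, 4861 to 7277 higher, 7780 to 11821 lower and 12483 to 15378 at least 2-fold. For NPC against proB they ran from 9243 to 15877 changed, 4710 to 7971 higher, 4533 to 7906 lower and 9242 to 12365 at least 2-fold. For liver against proB they ran from 11684 to 19145 changed, 6945 to 11913 higher, 4739 to 7232 lower and 11001 to 13325 at least 2-fold. Restricted genes ran from 971 to 1594 in ES, 1519 to 2097 in NPC, 3300 to 4142 in liver and 1537 to 2070 in proB, and lists past the test from 123 to 133. With a replicate block the counts were 9541, 15348, 9894, 15827, 12210 and 15947 in the order above. With the NPC arrays as 2 samples they were 14557, 16997, 11899, 18999, 15913 and 17479. Scan day as a block was not run, since it is aliased with NPC, and leaving out saturated genes was not run, since 0 spots were saturated. Slide as a fixed block could not be fitted for NPC. Signal over background limits the NPC arrays most, as 68.9 and 70.6% of their probes were well above it.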

Other observations

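The tests of explanations and of gene families in this part were chosen after the results were seen, while the gene lists and the scalings they use were fixed beforehand. Families were formed from the letters that open the symbols. Of 121 families with at least 15 genes, the beta protocadherins, adhesion molecules of a single gene cluster on chromosome 18, were higher in NPC than in ES: 15 of 21 rose and 0 fell, with a median log2 fold change of 2.34 (2.31 to 2.66 under the other scalings), camera adjusted p = 3.80e-08 and adjusted p = 0.785 with an estimated correlation. Between proB and ES 0 of the 21 were called with limma. In liver 68 of 77 Cyp genes rose against ES (median 5.67, adjusted p = 1.47e-14, 5.06 to 5.68 under the other scalings, adjusted p = 0.338 with an estimated correlation). All 15 carboxylesterase genes (Ces) rose there, with a median of 7.85 (5.88 to 7.78, camera adjusted p = 7.09e-08 and adjusted p = 0.322 with an estimated correlation). Ribosomal protein genes of the large subunit (Rpl) were lower in liver than in ES, 36 of 48 with 0 higher, a median of -0.96 (-1.50 to -1.10 under the other scalings), camera adjusted p = 2.23e-08 and adjusted p = 0.537 with an estimated correlation. In proB the mitochondrial ribosomal genes (Mrpl) were lower than in ES, 31 of 47 with 0 higher, a median of -1.04 (-1.04 to -0.78), camera adjusted p = 1.49e-06 and adjusted p = 0.861 with an estimated correlation.

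Olfactory receptor genes (Olfr), which textbook knowledge places in sensory neurons, were called higher in liver than in ES for 577 of 867, with a median of 0.88 (0.52 to 1.26 under the other scalings), camera adjusted p = 1.89e-10 and adjusted p = 0.552 with an estimated correlation. Over all genes 9426 of 25841 were called higher in liver, with a median of 0.31. Against liver 637 of the 867 were lower in NPC, with a median of -1.28 (-0.74 to -0.39), camera adjusted p = 2.47e-10 and adjusted p = 0.557 with an estimated correlation. Over all genes 10288 of 25841 were lower in NPC than in liver, with a median of -0.52. The signal of the Olfr genes over background was not examined, so the calls do not show that liver expresses olfactory receptors.

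Fibroblast and stromal genes differed between the ES arrays, by a median of 3.37 in favour of replicate 2. An effect of slide 2 is argued against by proB replicate 2, on the same slide, where the median against proB replicate 1 was -0.078. Loss of the pluripotent state across the sample is argued against by the pluripotency network, whose median differed by -0.13. Loss in a small share of the cells would lower that median little, so it cannot be judged here and stays open. Fibroblast RNA in the ES replicate 2 sample stays open as a candidate explanation, since the labels say that ES cells grew on irradiated mouse embryonic fibroblasts and, for another assay, were taken off them. The 27 of 28 members over 1 higher are the pattern itself, in which Tagln, Col1a1 and Col1a2, the brightest, were at 16.79, 16.50 and 16.41 in replicate 2 against 13.93, 12.95 and 13.24. Members of other lists were also over 1 higher in replicate 2, such as 16 of 37 Hox genes, 10 of 22 immediate early and dissociation genes and 8 of 24 imprinted genes. These lists were not drawn up as markers of fibroblasts, and no fibroblast sample was measured. They therefore do not tell fibroblast RNA from another cause. A difference between the cultures stays open and untested, as does one of strain, since the labels give the tag 4f2a to ES replicate 1 and not to replicate 2.

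Erythroid and myeloid genes were bright on both proB arrays, with 83.3% of the members of the lists called higher than in ES. An effect of 1 slide is argued against by a median absolute difference of 0.267 between the proB arrays, which were on different slides, and the scaling by a lowest list median of 3.63 over the other scalings. Other bone marrow cells in the samples stay open as a candidate explanation. Hba-a1 was at 18.29, S100a8 at 17.62 and Mpo at 16.45, while the labels describe selection for CD19, which would remove such cells, and then plating on OP9 stromal cells, and do not say at which stage the RNA was taken. Of the 16 erythroid genes higher than in ES 15 were also higher than in liver, as were 16 of 19 myeloid genes. In the macrophage list, which shares Lyz2 and Csf1r with the myeloid list, 18 of 19 genes were higher than in ES, with a median of 4.47, and 12 were lower in liver than in proB and 3 higher, with a median of -1.14 (adjusted p = 0.00552, and 0.53 with an estimated correlation), while of 26 T and NK cell genes 11 were higher than in ES and 2 lower. The lists do not tell which cells made the RNA. Expression of these genes by the pro-B cells themselves was not tested.

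More genes were called lower than higher in NPC against ES, with 44.1% of calls higher. The share was 54.6% with normexp and 59.0% with a shift to equal medians, and the median over all genes moved with it, from -0.18 to 0.69 and 0.14. With quantile normalization, the authors' values and the filter on all 8 arrays, where that median was 0.013, 0.0042 and 0.018, the share was 48.9, 51.5 and 55.7%. The majority of lower calls was thus lost with normexp, the shift to equal medians and the authors' values, and kept with quantile normalization. The filter on all 8 arrays drops by construction genes not detected in NPC. Among these were the 2276 genes called lower that were detected in ES alone, so its share decides nothing. As each of the 5 settings also moved the median of all genes up, the shares do not say which step is behind it. Low signal over background and the scaling of the arrays therefore cannot be told apart from a difference between the types. The slide and scan day of the NPC arrays cannot be told apart from the type, since 0 arrays of another type shared them. A difference between the cell types stays open and untested.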
